A study of Homo sapiens with 12 samples.

How the data were processed

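Gene expression was measured in THP-1 cells, a human monocytic leukaemia line, on 12 two-colour Agilent whole human genome oligonucleotide arrays. Cells had been exposed for 6 h to carbon nanotubes (CNT), gold nanoparticles (GNP), both, the antimicrobial peptide indolicidin, or combinations of these, and time-matched cells were left untreated. Per the series design text, RNA from 3 cultures of a condition was pooled in equal amounts, so each of the 12 conditions has 1 array and no array has a replicate. Cy5 carried the RNA of the condition and Cy3 carried a common reference made from all RNAs, per the labels. No dye swap was found among the labels.

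Per the file headers, the arrays were read with Agilent Feature Extraction 10.5.1.1, which gives median spot intensity and local background intensity in each channel. The deposited processed signals are intensities that this program background-subtracted, detrended and dye-normalised, per the file headers. The deposited log ratio is the log10 of processed Cy5 over processed Cy3, and the deposited series matrix holds the same log10 ratio rounded, with a median of 0 on every array. The deposited log10 ratio was 0 for 51.1% to 58.5% of the 43376 non-control spots of an array.

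The log2 ratios analysed here were computed from the median spot and background intensities, because the deposited files give no mean intensities, which the plan had named. Background was corrected with limma's normexp method with an offset of 50, and ratios were normalised within each array by loess with 4 iterations. Spots that the program marked as non-uniform or population outliers were set to missing, and replicate spots of a probe were averaged. Probes were named by matching RefSeq accessions to a reference gene table of assembly GRCh38.p14, used for names only because the array design was annotated to an older build. Of 28672 probes with a RefSeq accession, 27833 matched a gene, and 18479 genes were named. A gene was kept if its probe was well above background in Cy5 on at least 3 of the 12 arrays, and the probe with the highest mean intensity stood for the gene. This left 4089 genes with a name or a locus symbol.

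The share of spots well above background ran from 11.2% to 14.9% of an array in Cy5 and from 5.47% to 7.92% in Cy3, so most probes were too dim to be compared. 0 spots were saturated on any array. The number of arrays limits the precision. The spread of the Cy3 reference over the 12 arrays, which holds labelling and hybridisation error and no difference in RNA, had a median SD of 0.11 log2 per gene. The Cy5 signal had 0.14 and the log2 ratio 0.17. Over the 1203 genes well above background in Cy3 on all arrays these were 0.15, 0.23 and 0.17, and with median centring Cy3 had 0.32 and Cy5 0.39.

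All 12 sample columns were used and 0 were left out. The 9 arrays with nanomaterial cross 3 nanomaterials (CNT, GNP, CNT+GNP) with 3 peptide states (none, conjugated, spiked). An additive limma fit of peptide state and nanomaterial left 4 residual degrees of freedom, so the 3 nanomaterials served as the replicates of a peptide state and the reverse. The 6 contrasts of this fit were tested with limma's moderated test and Benjamini-Hochberg adjustment at 0.05 over 4089 genes. Each of the 11 treated arrays was set against the untreated array without a test. Genes at least 2-fold apart were counted among genes well above background in Cy5 on both arrays, beside the same count in the Cy3 reference. Here and in the fits, Cy3 counts come from a single channel and ratio counts from both. The measures are unlike, so Cy3 counts are not the chance level of ratio counts. The 22 gene lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, for lists with at least 3 measured members. For single arrays, the median of a list was placed among 10000 random lists of the same size matched on intensity in 10 bins.

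The tests, gene lists, alternatives and rule for naming genes were chosen before the data were examined. The rule names, for each contrast, up to 10 genes per direction with the largest difference among those past the threshold with the same sign in all 3 blocks, or the 5 lowest p in a direction where fewer than 5 pass. For single arrays it names the 5 largest differences each way, and for lists the members with the largest absolute difference. Locus and clone names are not named.

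Further comparisons were added after the data were seen. The 9 arrays with nanomaterial were compared with the 3 without by limma with slide as a block, because genes lowest on the array of CNT+GNP with spiked peptide were seen to be high on all 3 arrays without nanomaterial. The 3 arrays of each peptide state were compared with the lone untreated array, and with each lone indolicidin array, with the spread pooled from the 9 nanomaterial arrays. Array weights and a filter on both channels were added as well.

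The 6 contrasts were repeated with the Agilent log ratio, the series matrix, no background correction, median centring in place of loess, quantile-normalised Cy5 alone, no filter, a filter on all 12 arrays, only the 6 arrays of a contrast, all 12 arrays (for the 3 contrasts of peptide state), no block, the mean of a gene's probes, and with each array left out in turn. The single-array counts, the list tests and the added comparisons were repeated with those of these choices that applied. Array weights were estimated gene by gene, because limma's default estimate stopped before converging. Software was R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. The fits were tested on simulated data. In a simulation of the contrast of conjugated with spiked over 3971 genes, the fit recovered 43% of genes changed by 0.5 log2 and 94% of those changed by 1 log2, with 6 false calls. The fit of nanomaterial against none recovered 69% and 99%, with 11 false calls. The simulation drew each gene independently with the residual spread of the nanomaterial arrays, and held no slide or position effect. These shares and false calls therefore need not hold for the real arrays.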

Results

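The data describe 12 conditions of THP-1 cells after 6 h, with 1 array each made from 3 pooled cultures. The 3 conjugated conditions (CNT, GNP and CNT+GNP carrying indolicidin) and the untreated cells lay on slide 1. The 3 nanomaterials without peptide and indolicidin alone at 20 µg/ml lay on slide 2. The 3 nanomaterials spiked with indolicidin and indolicidin alone at 0.02 µg/ml lay on slide 3. The peptide dose of the conjugated and spiked arms is not given in the labels. Peptide state and slide therefore coincide, and on each slide CNT, GNP, CNT+GNP and the array without nanomaterial take positions 1, 2, 3 and 4. Of 4089 genes tested, 2529 were well above background in Cy5 on all 12 arrays, and 1203 in both channels.

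Whether attaching the peptide to the nanomaterial differs from adding it free was asked by comparing conjugated with spiked arrays (n = 3 against 3). FBXO22, a substrate receptor of a ubiquitin ligase, was higher in conjugated arrays by 1.02 log2 (SE 0.12, limma adjusted p = 0.00513), and RPN2, a subunit of the oligosaccharyltransferase that glycosylates proteins in the endoplasmic reticulum, by 1.04 (SE 0.13, adjusted p = 0.00596). ATP2A2, the calcium pump of the endoplasmic reticulum, was higher by 1.09 (SE 0.21) and HNRNPH1, an RNA-binding splicing regulator, by 1.05 (SE 0.15). The histone H4 genes H4C8 and H4C11 were lower in conjugated arrays, with differences of -0.92 (SE 0.16) and -0.87 (SE 0.16), and so was the proteasome subunit PSMB2, at -0.73 (SE 0.13). Near-identical histone H4 genes can share a probe's signal.

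The remaining higher genes named by the rule were TPM4, a tropomyosin (0.91), TSNAX (0.86), THOC1, a subunit of the complex that couples transcription to mRNA export (0.84), the chaperone HSPA8 (0.77), the pseudogene SDHAP1 (0.75) and BZW1 (0.75). ADAMTS7, a secreted metalloprotease, differed by -0.67, with -1.78 on Cy5 alone and -0.62 in the Cy3 reference, so both channels were lower. COXFA4, a respiratory chain subunit, differed by -0.64. In total limma called 19 genes higher and 5 lower, all 24 with the same sign in the CNT, GNP and CNT+GNP pairs, and 421 genes had an unadjusted p under 0.05 where chance gives 204.5. The same fit on the Cy3 reference, where no RNA differs, called 1 gene and had 395 under 0.05, about as many as the ratios. A single channel and a ratio are unlike measures, however. The count fell to 0 without the GNP conjugate array or the CNT+GNP conjugate array, to 2 without the GNP spiked array, and to 8 without the CNT conjugate array or without the CNT+GNP spiked array. It was 0 with the Agilent log ratios, where the 24 genes had a median signed difference of 0.99 log2 against 0.75 and a residual SD of 0.25 against 0.155. It was 0 without the nanomaterial block, where the difference was 0.75 and the residual SD 0.199. With 1 array left out the 24 kept their signs, with medians from 0.72 to 0.84. Because slide and peptide state coincide, a slide difference in Cy5 cannot be told apart from a difference in state.

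**Figure D1:**
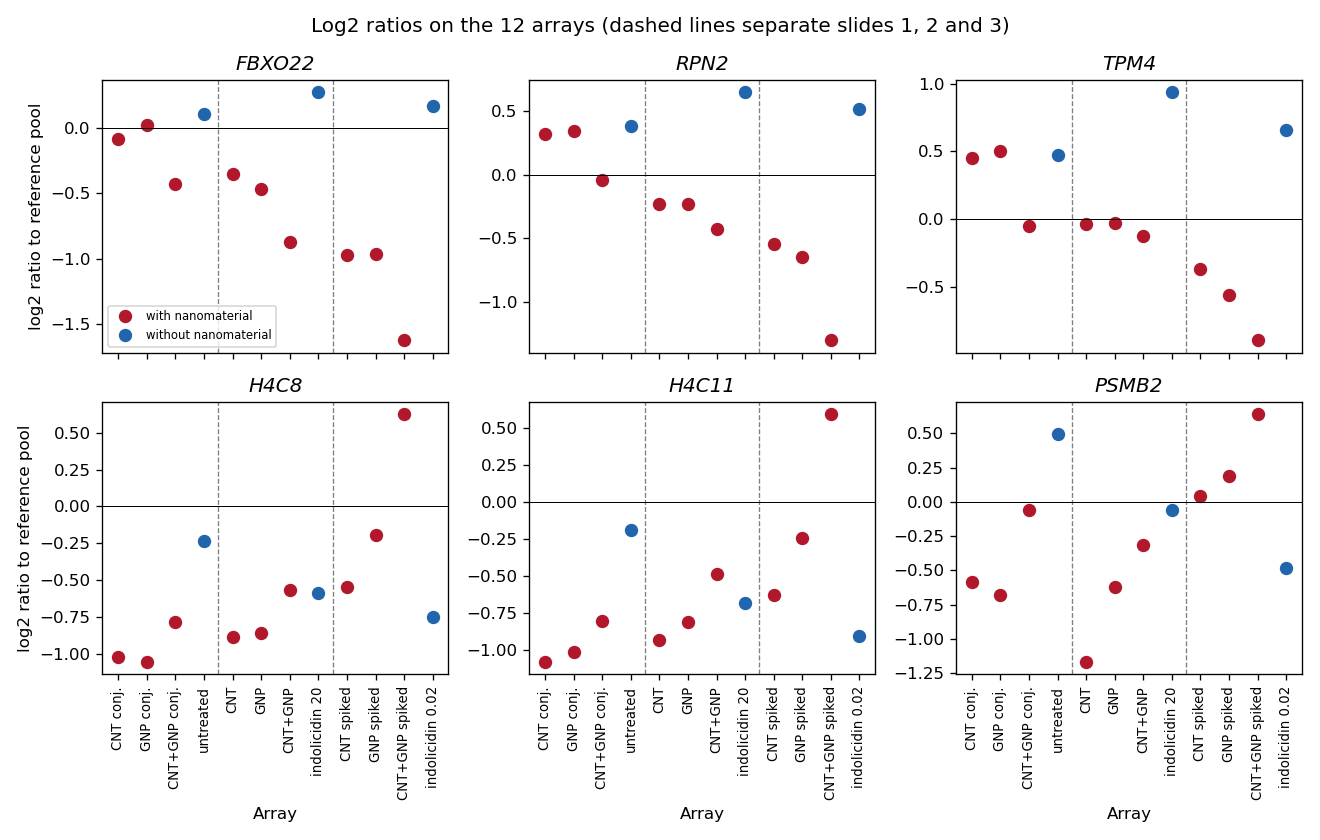
Log2 ratio to the reference pool for 6 genes called between conjugated and spiked arrays, 1 point per array, with dashed lines between the 3 slides. FBXO22 reached -1.63 on the CNT+GNP spiked array and 0.02 on the GNP conjugate array, and H4C8 reached 0.63 and -1.06 on the same arrays.

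Among the fixed gene lists in this contrast, heat shock genes had 4 of 7 measured members higher (median 0.26), with HSPA8 past the threshold and HSP90AB1 at 0.45. Hypoxia and glycolysis genes had 6 of 8 higher (median 0.07, LDHA 0.54, PGK1 0.43), and the metallothionein list had 6 of 7 lower (median -0.21, MT1X -0.44, MT1G -0.29). Metallothioneins bind zinc and copper, and the 7 measured members include MTF1, which is not a metallothionein. Ribosomal proteins had 16 of 24 lower (median -0.12, RPS20 -0.43). Camera called 0 of the 21 lists tested, with a lowest adjusted p of 0.0738 for both the ribosomal and the glycolysis list and 0.0883 for metallothioneins, while fry called 0 by direction and 6 without regard to direction: metallothioneins, heat shock, glycolysis, Toll-like receptor, macrophage and lysosomal genes. With an estimated correlation the lowest adjusted p was 0.807. Counts adjusted over the list alone were 2 for heat shock genes, 2 for hypoxia and glycolysis, 2 for Toll-like receptor genes, 2 for macrophage markers, 1 for metallothioneins, 1 for lysosomal genes and 1 for respiratory chain genes. The monocyte co-receptor CD14, at 0.61, belongs to the Toll-like and macrophage lists. Over all genes tested 1 heat shock gene and 1 respiratory chain gene passed, and the other lists had 0.

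The medians of the other lists in this contrast lay between -0.14 and 0.10. They were 0.09 for inflammatory cytokines, -0.10 for interferon-stimulated genes, -0.06 for anti-inflammatory genes, -0.08 for Toll-like receptor genes, -0.09 for macrophage markers (mean 0.05), -0.0007 for oxidative stress genes and -0.14 for unfolded protein response genes. For p53 targets the median was 0.10, for apoptosis regulators -0.08, for cell cycle genes -0.11, for immediate early genes 0.02, for cholesterol efflux genes -0.09 and for lysosomal genes 0.02. Inflammasome genes had -0.10, respiratory chain genes -0.0071, lymphoid and granulocyte markers 0.0041, and epithelial and stromal markers -0.01. Cholesterol synthesis genes had 2 measured members and were not tested. UCP3, a mitochondrial carrier, was well above background in spiked arrays and not in conjugated ones. Its mean Cy5 signals were 6.50 and 6.16 log2, a measured 1.27-fold difference, and it did not pass. None of the 3 largest such differences of any contrast passed.

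PSMB2 was the gene that separated spiked nanomaterials from nanomaterials alone, at 0.99 log2 higher (SE 0.13, limma adjusted p = 0.0244, n = 3 against 3, same sign in all 3 pairs). H4C8, at 0.74, and the depalmitoylating enzyme ABHD17C, at 0.60, did not pass, nor did FBXO22 at -0.62, TSNAX at -0.60 or THOC1 at -0.56. Limma called 1 gene higher and 0 lower, and 257 genes had an unadjusted p under 0.05, where the Cy3 reference had 344. Camera called 0 of 21 lists, and counts adjusted over the list alone were 1 for heat shock, 1 for glycolysis and 1 for respiratory chain genes, with 0 over all genes. The call was kept when the GNP array without peptide was left out, and the count was 0 when any other of the 9 arrays was left out: CNT conjugate, GNP conjugate, CNT+GNP conjugate, CNT alone, CNT+GNP alone, CNT spiked, GNP spiked or CNT+GNP spiked. PSMB2 differed by 0.86 to 1.12 in these 9 fits. The count was also 0 with Agilent log ratios, where PSMB2 differed by 1.17 with a residual SD of 0.254 against 0.164, and the contrast compares slide 3 with slide 2.

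Conjugated nanomaterials were compared with the same nanomaterials alone to ask what attached peptide adds. RPN2 differed by 0.50 log2 (SE 0.13), HNRNPH1 by 0.47 (SE 0.15) and FBXO22 by 0.40 (SE 0.12), while EGLN1, an oxygen-sensing prolyl hydroxylase, differed by -0.50 (SE 0.12) and GALK2 by -0.49 (SE 0.13). EGLN1 had a Cy5 difference of 0.17 and a Cy3 difference of 0.34, and GALK2 had -0.05 and 0.20. Both were well above background in Cy3 on 0 nanomaterial arrays, so their ratios rest on a dim reference. None of these passed: limma called 0 genes, the lowest adjusted p was 0.985, and 176 genes had an unadjusted p under 0.05 against 204.5 by chance and 313 in the Cy3 reference. Inflammatory genes gave a median of 0.04 and a mean of -0.0014 over 5 measured members, and camera called 0 of 21 lists.

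The type of nanomaterial was compared over the 3 peptide states, each on its own slide. CNT, GNP and CNT+GNP kept the same array position on every slide, so position cannot be told apart from nanomaterial in these contrasts. Between GNP and CNT, ARMC6 differed by 0.71 log2 (SE 0.16) and the ceramide synthase CERS4 by -0.43 (SE 0.15), and limma called 0 genes with 121 at an unadjusted p under 0.05. On Cy5 alone ARMC6 had -0.10 and CERS4 0.06, where Cy3 had -0.34 and 0.15, and 7 of the 10 genes named in this contrast had the opposite sign. All 10 were well above background in Cy3 on 2 or fewer nanomaterial arrays, so their ratios rest on a dim reference. Between CNT+GNP and CNT, PSMB2 differed by 0.66 (SE 0.13), H4C11 by 0.65 (SE 0.16) and FBXO22 by -0.51 (SE 0.12), and limma called 0 genes with 181 at an unadjusted p under 0.05. Between CNT+GNP and GNP, ABHD17C differed by 0.46 (SE 0.13) and HSPA8 by -0.52 (SE 0.14), and limma called 0 genes with 217 at an unadjusted p under 0.05. The Cy3 reference in the same fits gave 0, 4 and 0 called genes and 276, 584 and 230 under 0.05.

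Ribosomal protein genes stood higher in the mixture, with 23 of 24 measured members positive against CNT (median 0.15 log2, RPS20 0.38, RPLP1 0.35) and 20 of 24 against GNP (median 0.12, RPS14 0.30). Camera gave adjusted p = 0.000718 and 0.0311 for this list, and adjusted p = 0.814 and 0.954 with an estimated correlation. Counts of its members were 0 over all genes and 0 adjusted over the list alone, while the heat shock list, with 0 over all genes, had 2 against CNT and 1 against GNP adjusted over the list alone, and immediate early genes had 1 against GNP. Both calls were lost without the CNT+GNP spiked array (adjusted p = 0.902 and 0.895), the first without the CNT spiked array (0.484), and the second without the GNP spiked array (0.554) or the GNP array without peptide (0.0897). Camera called 0 of 21 lists between GNP and CNT. The mixture lay at the same array position on every slide, so position cannot be told apart from the mixture here either.

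HNRNPH1 was the gene furthest from the arrays without nanomaterial, lower by -1.27 log2 on the 9 arrays with nanomaterial than on the 3 without (SE 0.17, limma adjusted p = 0.00124), in a comparison added after the data were seen. BZW1 followed at -1.10 (SE 0.12, adjusted p = 0.000119), CNEP1R1, a regulator of the lipin phosphatase at the nuclear envelope, at -0.92 (SE 0.10), THOC1 at -0.91 (SE 0.14) and the splicing factor SRSF9 at -0.77 (SE 0.11). The pseudogene SEPTIN7P14 had -0.97, FBXO22 -0.82, RPN2 -0.82, HSPA8 -0.82 and TPM4 -0.81. HSPA8 turned to 0.79 on Cy5 alone, where its Cy3 difference was 1.30, so both channels were higher. Higher genes were WDR83OS, a chaperone of membrane protein insertion (0.62, SE 0.13), the chromatin remodeller CHD8 (0.49, SE 0.09) and the vesicle tethering subunit TRAPPC1 (0.48). The nuclear pore protein NDC1 (0.46), SLAIN2 (0.45), MAD2L2 (0.44), FASTK (0.41), SMIM29 (0.41) and RPL10L (0.38) were higher as well. On Cy5 alone NDC1 had 0.10 and TRAPPC1 0.28, where Cy3 had -0.35 and -0.24.

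Of 4089 genes, limma called 9 higher and 52 lower, 57 of these 61 with the same sign on all 3 slides. Among the 61 were 15 of the 24 genes called between conjugated and spiked arrays, so the 2 results are not separate. By ratio 507 genes had an unadjusted p under 0.05. The same fit on the Cy3 reference, a single channel and an unlike measure, had 670. The median difference of the lower genes was -0.39 on slide 1, -0.60 on slide 2 and -0.81 on slide 3. The count was 5 without indolicidin at 20 µg/ml, 6 without indolicidin at 0.02 µg/ml, 21 without CNT+GNP conjugate, 22 without CNT+GNP alone, 22 without GNP spiked, 33 without GNP alone, 43 without the untreated array and 148 without CNT+GNP spiked. In these fits the 61 genes kept their signs, with median signed differences from 0.46 to 0.66 log2. The count was 8 with Agilent log ratios, where their median was 0.75 against 0.55 and the residual SD 0.262 against 0.168. Median centring turned the balance, with 286 higher and 11 lower, 16 of the 61 among them, and 9 genes were called in the Cy3 reference. The Cy3 signal deviated from the median array by an SD of 0.172, 0.151 and 0.307 log2 on the untreated, 20 µg/ml and 0.02 µg/ml arrays, and by 0.0959 to 0.1235 on the 9 others. Among the lists, HSPA8 and PGK1 passed over all genes, and counts adjusted over the list alone were 2 for Toll-like receptor genes and for macrophage markers and 1 for each of heat shock, p53, immediate early, lysosomal and glycolysis genes. Camera called 0 of 21 lists, with a lowest adjusted p of 0.322 and 0.773 with an estimated correlation.

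**Figure D2:**
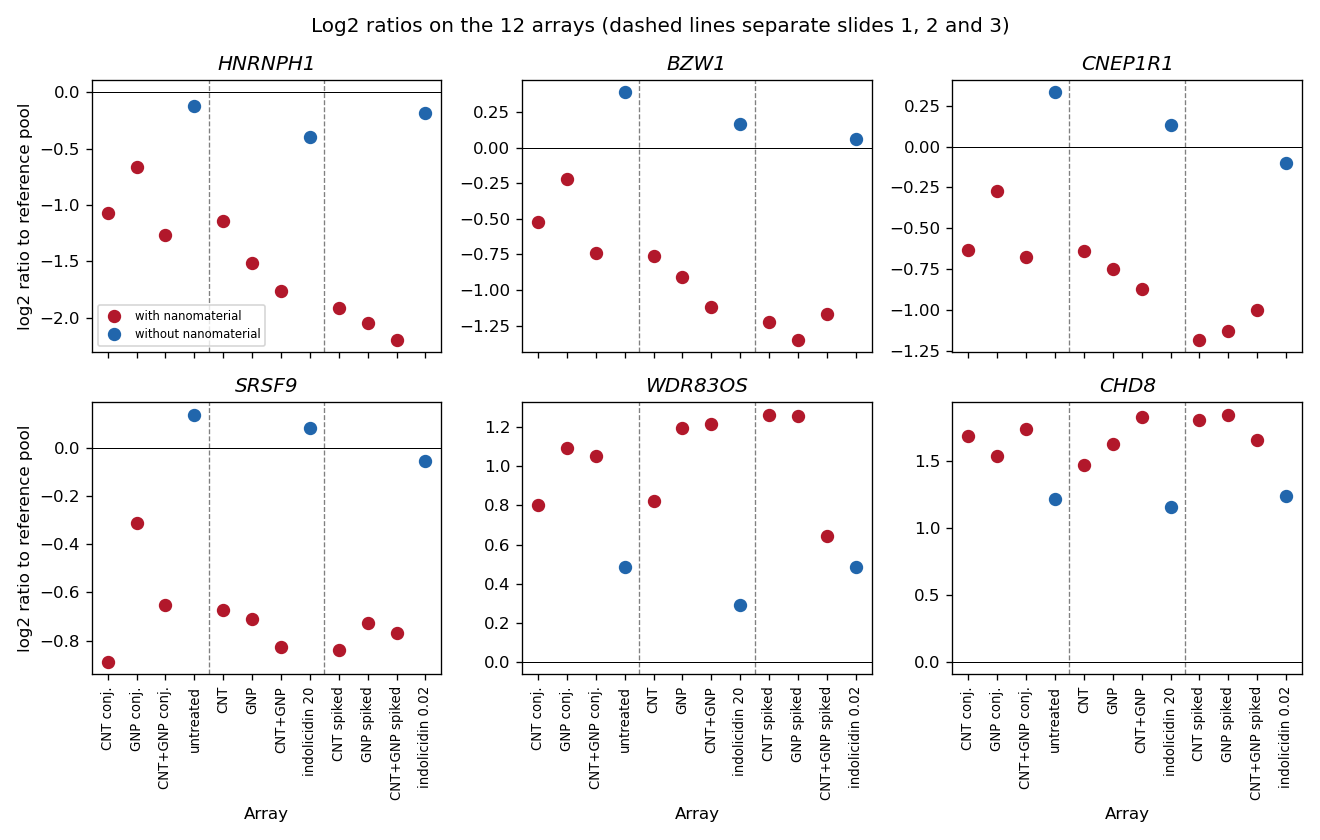
Log2 ratio to the reference pool for 6 genes called between arrays with and without nanomaterial, 1 point per array, with dashed lines between the 3 slides. BZW1 lay at 0.39, 0.17 and 0.06 on the arrays without nanomaterial and between -1.35 and -0.22 on the 9 others.

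Set against the lone untreated array, in comparisons also added after the data were seen, the 3 spiked arrays had 5 genes higher and 20 lower by limma, with HNRNPH1 at -1.93, THOC1 at -1.47 and BZW1 at -1.64. The 3 arrays of nanomaterial alone had 3 higher and 5 lower, with BZW1 at -1.32. The 3 conjugated arrays had 1 gene higher, ASF1B, a histone chaperone, at 1.61, where the Cy3 reference differed by -1.04. The Agilent log ratios called 0 genes in all 3. Against indolicidin at 20 µg/ml the counts were 6 higher and 1 lower (conjugated), 15 and 31 (spiked) and 7 and 4 (alone), and against indolicidin at 0.02 µg/ml they were 1 and 0, 3 and 17, and 1 and 0. These counts only describe the arrays, since the fits assume that the lone array varies like the others, and the Cy3 signal of all 3 lone arrays deviated more than that of any nanomaterial array.

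Single arrays were set against the untreated array to describe each treatment, with no replicate check. The CNT+GNP spiked array had the most genes 2-fold apart by log2 ratio, with 3 higher and 47 lower. Other settings ranked others first: with Cy5 alone indolicidin at 0.02 µg/ml had 161 against its 126, with median centring CNT conjugate 262 against 94, and with no filter CNT alone 140 against 85. The 0.02 µg/ml array had 4 genes apart by ratio and 79 in the Cy3 reference. All 79 had the same sign in Cy5, so its Cy5 count holds a deviation shared with the reference. On the CNT+GNP spiked array HNRNPH1 had -2.07 log2 and HCCS, the enzyme that attaches haem to cytochrome c, -1.94. ATP2A2 had -1.86, THOC1 -1.83 and DNAJC10 -1.81, and the Cy3 differences of these genes ran from -0.28 to 0.05. SF3B6, a splicing factor, had 1.04 and PFDN5, a prefoldin subunit, 0.93. The Cy3 reference had 11 genes 2-fold apart between the same arrays.

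The other arrays had fewer genes 2-fold apart. The counts were 16 for CNT conjugate, 13 for GNP conjugate, 9 for CNT+GNP conjugate, 21 for CNT alone, 23 for GNP alone, 21 for CNT+GNP alone, 21 for CNT spiked and 23 for GNP spiked. The Cy3 reference gave 13, 16, 12, 15, 13, 20, 13 and 14 in the same order. On the CNT spiked array HNRNPH1 had -1.79 and BZW1 -1.62, and on the GNP spiked array HNRNPH1 had -1.93 and CNEP1R1 -1.46. On the CNT conjugate array the histone H3.3 gene H3-3A had -1.77 and EIF4A1, a translation initiation helicase, -1.20. The 11 comparisons share 1 untreated array, so a gene that deviates there recurs in all of them. Of the 110 largest differences named over the 11 arrays, 64 were larger in Cy3 than in Cy5. ASF1B, with log2 differences from 1.28 to 1.73 over the 11 arrays, had a median Cy3 difference of -1.07 and a median Cy5 difference of -0.18, and LARS1, a leucyl-tRNA synthetase, had -0.90 and -0.44. ALPP, at -3.34 on the GNP array without peptide, had a Cy3 difference of 2.05. ASF1B was not well above background in Cy5 on every array. Of the 2529 genes that were, 0 were at least 2-fold apart the same way on all 11 treated arrays.

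**Figure D3:**
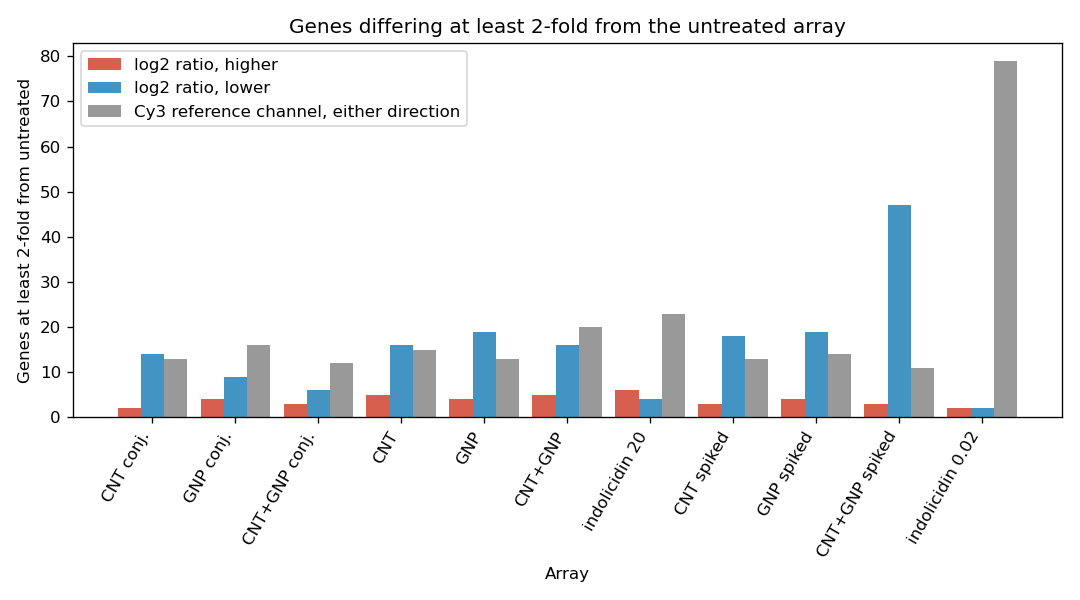
Number of genes at least 2-fold higher or lower than on the untreated array by log2 ratio, and number at least 2-fold apart in the Cy3 reference, for each of 11 treated arrays. The CNT+GNP spiked array had 47 lower genes, and the array of indolicidin at 0.02 µg/ml had 79 genes apart in Cy3.

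Indolicidin alone was measured at 2 doses. The median of the metallothionein list stood highest at 20 µg/ml. Over 7 measured members it was 0.55 log2 above untreated, at percentile 100 of 10000 random lists. MT1X had 1.00 and MT1G 0.88, and their Cy5 differences were 1.22 and 0.92, with Cy3 differences of 0.09 and -0.05. MT1B had 0.64, with a Cy5 difference of -0.21 and a Cy3 difference of -0.48. MT3, with a ratio of 0.07 against 0.25 untreated, and MTF1, with 0.11 against 0.17, were lower. MT1E had a ratio of 0.107 against 0.057 untreated, and 0.178 on CNT+GNP spiked. MT1B was higher on CNT+GNP alone (0.45 against 0.28). Against untreated, 10 genes were at least 2-fold apart at 20 µg/ml, among them the apelin gene APLN at 1.05 (Cy5 1.83) and ITGA7 at 1.06, while Cy3 had 23. The largest, SHD at -2.02, had a Cy3 difference of 1.34. Of the 10 differences named by the rule here, 7 were larger in Cy3 than in Cy5. At 0.02 µg/ml 4 genes were 2-fold apart and Cy3 had 79. Between the doses 9 genes were 2-fold apart, and 77 genes were apart in Cy3. The largest were PPP1CB at -1.95, STXBP4 at 1.905 and SHD at -1.87, with Cy3 differences of 1.35, -1.70 and 1.36. APLN had 1.24 (Cy5 1.90) and the kinase DYRK1A 1.02 (Cy5 1.59). Of the 10 differences named by the rule between the doses, 6 were larger in Cy3 than in Cy5. Metallothionein genes share sequence, so a probe can read more than 1 of them.

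**Figure D4:**
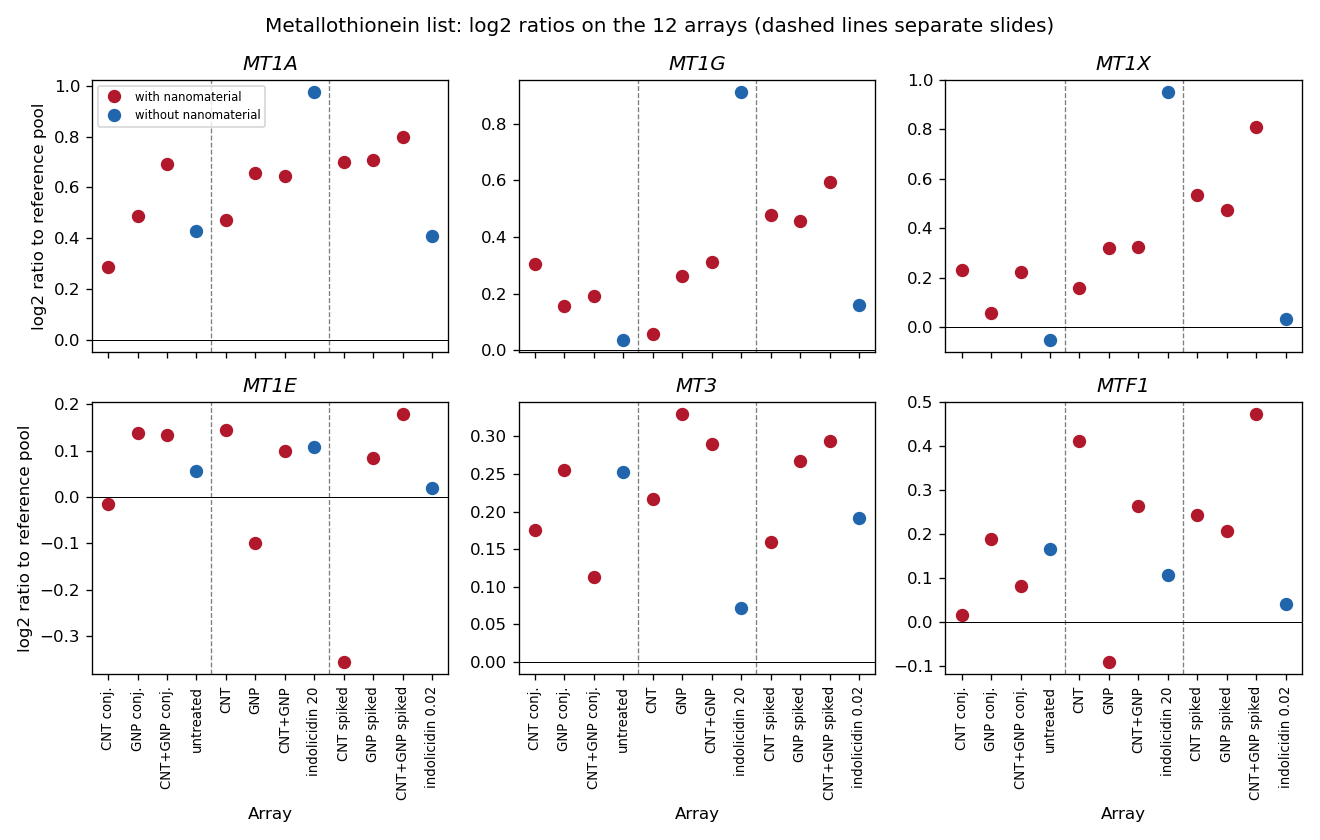
Log2 ratio to the reference pool for 6 members of the metallothionein list on the 12 arrays, 1 point per array, with dashed lines between the 3 slides. MT1X lay at 0.95 on the array of indolicidin at 20 µg/ml, 0.03 at 0.02 µg/ml and -0.05 on the untreated array.

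Other lists stood apart on single arrays. Metallothioneins lay at percentile 99.9 on the CNT+GNP spiked array (median 0.37) and 98.5 on the GNP spiked array (0.28). Ribosomal proteins lay at percentile 100 on the CNT+GNP spiked array (0.31, with RPL7 at 0.69 and RPL37 at 1.38, the latter with a Cy3 difference of -0.71). They lay at 0.7 on the array of indolicidin at 20 µg/ml (median -0.19 of 22 measured members). On that array RPLP1 had -0.394, while RPL37 had 0.70, with a Cy3 difference of -0.555, and RPL4 had 0.386. On the CNT+GNP spiked array hypoxia and glycolysis genes lay at 0.38 (median -0.38, PGK1 -1.02, LDHA -0.85). Immediate early genes lay at percentile 0.09 on the GNP array without peptide (median -0.38, KLF6 -0.49, JUN -0.46), at 1.14 on CNT+GNP alone (-0.23) and at 1.83 on CNT+GNP spiked (-0.30). The p53 targets lay low on 4 arrays, at percentile 0.97 on GNP alone (median -0.33, BTG2 -0.38, GADD45A -0.35), 1.27 on CNT spiked (-0.32), 1.32 on GNP spiked (-0.30) and 1.89 on CNT+GNP alone (-0.25). Neither list was particular to these arrays: the medians of both were negative on all 11 arrays, below percentile 10 on 9 for immediate early genes and on 10 for p53 targets. A high value on the shared untreated array would give the same. The anti-inflammatory list had medians of 0.37 on GNP alone, 0.39 on CNT+GNP alone and 0.47 on CNT spiked, with TGFB1 at 0.67, 0.65 and 0.82 and SOCS1 at -0.38 on the second. Its median was likewise above 0 on all 11 arrays and above percentile 90 on 6, which a low value on the untreated array would give. In all, 19 of 231 pairs of list and array lay outside the middle 95% of random lists. These pairs share the untreated array and some lists share members, so the count has no spread to be judged against.

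Arrays were compared by the correlation of log2 ratios across genes, which are not independent replicates. The CNT+GNP spiked array had a median r of 0.57 with the others, and the other 11 arrays had medians from 0.69 to 0.81. With the Agilent log ratios the lowest median was 0.51, for indolicidin at 0.02 µg/ml, and CNT+GNP spiked had 0.54. Over the 9 nanomaterial arrays, peptide state held 29.7% of the variance and nanomaterial 23.2%, where chance gives 25% each, and the Cy3 reference gave 28.2% and 29.4%.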

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

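The tests of explanations in this part were chosen after the results were seen, while the counts of the 6 contrasts and the fit without the CNT+GNP spiked array were planned.

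Genes such as HNRNPH1, BZW1 and SRSF9 were lower on the 9 arrays with nanomaterial than on the 3 without, on every slide, in a comparison that was itself found in these data. Of 64 choices of 1 array per slide as the odd one, 1 gave as many as the real 61 called genes, the real one, and the highest other gave 6. The median Cy3 difference of the called genes, signed by their ratio difference of 0.55 log2, was 0.019. This argues against the reference channel for the 61 as a set, but not for each gene. HSPA8 and UNC50, lower by ratio, were higher on Cy5 alone (0.785 and 0.605), with Cy3 differences of 1.297 and 1.127. Both channels rose in these genes, so the values do not assign their ratio differences to the reference alone. FUNDC1 and IER5, lower by ratio at -0.472 and -0.592, had 0.145 and 0.057 on Cy5 alone and 0.464 and 0.481 in Cy3. NDC1, higher by ratio at 0.459, had 0.096 on Cy5 alone and -0.348 in Cy3. In the fit without the untreated array the 61 had a median signed difference of 0.656 (median SE 0.135) against 0.554 (0.113) with it. There 38 were called again, the other 23 having 0.502 (0.13) against 0.474 (0.103). The 61 were picked with the other slides in the fit and kept their signs whichever array was left out. The fit therefore does not decide whether the untreated array drove the calls. Without either indolicidin array 5 of the 61 were called again. An effect of array position on Cy5 cannot be told apart, since 0 slides had the array without nanomaterial at another position. The arrays without nanomaterial also had the lowest shares of spots well above background in Cy3. These were 5.47% untreated and 5.80% and 5.50% with indolicidin at 20 and 0.02 µg/ml, against 6.04% to 7.92% on the 9 others. In Cy5 their 11.2% to 12.2% overlapped the 11.7% to 14.9% of the others. A response to nanomaterial may be a reading, as may position or lower signal, and these were not told apart.

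FBXO22, RPN2 and the other genes called between conjugated and spiked arrays had a median signed Cy3 difference of -0.028 log2 against a ratio difference of 0.75, which argues against the reference channel. In the fit without the CNT+GNP spiked array the 24 had a median signed difference of 0.729 (median SE 0.131) against 0.754 (0.127) with it. In that fit 8 were called again by limma. The other 16 had 0.673 (0.134) against 0.722 (0.127), with limma adjusted p from 0.0527 to 0.214 on 1 residual degree of freedom fewer. The 24 were picked with that array included and had the same sign in all 3 nanomaterial pairs, so a median near zero was unlikely. The fit therefore does not decide whether that array drove the calls. The untreated array minus indolicidin at 0.02 µg/ml, from the same slides, differed by -0.09, but with 1 array per slide a slide effect on Cy5 cannot be told apart from peptide state. The way the peptide was given stays open as an untested biological explanation.

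The CNT+GNP spiked array correlated least with the others by loess ratios, while by Agilent log ratios indolicidin at 0.02 µg/ml did (median r 0.51 against 0.54). Its Cy3 signal deviated from the median array by an SD of 0.104 log2, below the median of 0.114 over the 12 arrays, which argues against a fault shared by both channels. Its 11.7% of spots well above background in Cy5 was low but above that of 1 array, so a lower signal cannot be told apart. RNA quality and transcript length were not tested, and a biological response of these cells stays open as untested.

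For the 6 contrasts, 6 arrays make 10 splits, too few for a share under 0.05. The real count and the highest other were 0 and 1 for conjugated against alone, with 10 splits giving as many, and 1 and 0 for spiked against alone, with 1 split. They were 24 and 0 for conjugated against spiked, with 1 split, and 0 and 0 for the 3 nanomaterial contrasts, with 10 splits each.

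In the Cy3 reference, which the comparisons do not use on its own, the array of indolicidin at 0.02 µg/ml had 79 genes at least 2-fold from the untreated array, where the 10 other treated arrays had 11 to 23. Of these, 63 were lower and 16 higher, and all 79 had the same sign in Cy5, with a median of 1.85 log2 signed by the Cy3 difference.

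The difference between arrays with and without nanomaterial varied between slides for a few genes by limma's interaction, but each slide has 1 array without nanomaterial, so these calls rest on single arrays and show no more than that such an array deviated. Between slides 1 and 3 it did for 1 gene, STXBP4, between slides 2 and 3 for 4 (STXBP4, SHD, PPP1CB and ADAT3), and between slides 1 and 2 for 2 (SHD and ADAT3). STXBP4 had a Cy3 difference of -1.73 on slide 3, and on slide 2 SHD had -1.28, PPP1CB -1.20 and ADAT3 -1.06.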

How the results depend on the processing

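The array weights, the filter on both channels, the comparison of arrays with and without nanomaterial and those with the lone untreated array, with their alternatives, were chosen after the data were seen, and the other alternatives before the data were examined. Low signal over background limits all of these results, since at most 14.9% of the spots of an array were well above background in Cy5. The cause of each change below was not tested.

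Counts of 0 for conjugated against alone and for the 3 nanomaterial contrasts were 0 under each alternative run. A count of 1 for spiked against alone became 0 with Agilent log ratios, median centring, the series matrix, no filter, only the 6 arrays, all 12 arrays and no block, and ran from 0 to 1 with 1 array left out. The 24 genes (19 higher, 5 lower) of conjugated against spiked became 0 with Agilent log ratios, the series matrix and no block, and 9 with no filter, 13 with all 12 arrays, 39 with array weights and 55 with both channels above background. They became 133 (130 higher, 3 lower, 20 of the 24 among them) with median centring and 66 (45 higher, 21 lower, 15 of the 24) with Cy5 alone, and ran from 0 to 32 with 1 array left out. In spiked against alone, Cy5 alone called ADAMTS7 (1.22 log2) in place of PSMB2.

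The 61 genes (9 higher, 52 lower) of nanomaterial against none became 8 (3 higher, 5 lower, 4 of the 61 among them) with Agilent log ratios and 8 with the series matrix. They became 297 (286 higher, 11 lower, 16 of the 61) with median centring, which moved the median of all genes by 0.13 log2, and 220 (54 higher, 166 lower, 36 of the 61) with Cy5 alone, where HSPA8 reversed to 0.79. The count was 20 with no filter, 93 with Cy5 above background on all arrays, 124 with both channels above background, 21 with no slide block and 146 with array weights, and ran from 5 to 148 with 1 array left out. With Agilent log ratios and the series matrix the called genes of these 3 comparisons kept their signs, with larger differences and a larger residual SD. Against the lone untreated array, the counts of 1, 8 and 25 for conjugated, alone and spiked arrays became 0, 0 and 0 with Agilent log ratios, and 115 (52 higher, 63 lower), 209 (89 higher, 120 lower) and 356 (130 higher, 226 lower) with Cy5 alone.

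Counts of genes at least 2-fold apart follow in the order CNT, GNP and CNT+GNP conjugate, CNT, GNP and CNT+GNP alone, indolicidin at 20 µg/ml, CNT, GNP and CNT+GNP spiked, indolicidin at 0.02 µg/ml, and the higher against the lower dose, with the number higher in parentheses. As reported they were 16 (2), 13 (4), 9 (3), 21 (5), 23 (4), 21 (5), 10 (6), 21 (3), 23 (4), 50 (3), 4 (2) and 9 (5). With Agilent log ratios they were 618 (173), 553 (243), 529 (273), 575 (334), 598 (306), 572 (281), 476 (288), 642 (385), 591 (206), 671 (174), 493 (311) and 442 (210). With the series matrix they were 617 (173), 553 (243), 528 (273), 574 (334), 598 (306), 572 (281), 475 (288), 641 (384), 591 (206), 671 (174), 491 (309) and 440 (209). With median centring they were 262 (262), 23 (19), 23 (18), 36 (34), 53 (47), 42 (34), 11 (7), 70 (60), 50 (39), 94 (4), 24 (3) and 45 (40). With Cy5 alone they were 59 (29), 40 (22), 44 (20), 66 (26), 61 (27), 62 (23), 45 (9), 96 (40), 80 (25), 126 (29), 161 (42) and 168 (127). With no filter they were 43 (29), 80 (29), 73 (32), 140 (33), 120 (31), 127 (32), 84 (36), 87 (33), 68 (31), 85 (30), 38 (29) and 64 (15). Median centring moved the median of all genes by 0.41, 0.22, 0.15, 0.26, 0.22 and 0.17 log2 in the first 6 of these comparisons, by 0.12 for CNT spiked and by 0.20 for GNP spiked. It moved that median by 0.13 for conjugated against spiked and by -0.13 for CNT+GNP against CNT. For indolicidin at 0.02 µg/ml the Agilent log ratios moved it by 0.11 and Cy5 alone by 0.14, and Cy5 alone moved it by -0.18 between the doses.

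The 2 list calls became 0 with an estimated correlation and 0 with Agilent log ratios, and ran from 0 to 3 with 1 array left out. The median correlation between arrays was 0.758 and became 0.578 with Agilent log ratios. Of the values of single genes named in the 6 contrasts, 1190 kept their direction and their side of the threshold, 155 fell below it, 16 changed sign without having passed and 1 rose past it. For nanomaterial against none these were 299 kept, 135 below and 1 reversed, and for single arrays 398 values moved by more than the spread and 82 did not. For the 6 contrasts slide as a block was not run, because slide and peptide state coincide. The nanomaterial block already pairs arrays in the main fit of the peptide contrasts, and no pairing of cultures was possible because each condition has 1 array.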

Other observations

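Of the 27 inflammatory cytokine and NF-kB genes, 5 were bright enough to be measured. TNF, the tumour necrosis factor gene, had log2 ratios between 0.18 and 0.60 on 11 arrays and -0.38 on the CNT+GNP spiked array. NFKB2, a subunit of NF-kB, lay between 0.03 and 0.36 on all 12 arrays. Both were picked as examples after their values were seen, and no test was run on them beyond those of their list.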
